A study of Mus musculus with 12 samples.

How the data were processed

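Gene expression was measured on 12 one-colour Affymetrix mouse arrays, 3 for each of 4 groups: virgin lung, pregnant lung, virgin liver and pregnant liver of NOD/SCID mice. Per the submitters' processing notes, tissue was ground in liquid nitrogen, RNA was extracted on columns and labelled with biotin, and RNA of 2 mice was pooled for each array. The deposited values are log2 expression values that the authors computed with RMA, which corrects background, normalizes between arrays and summarises each probe set. The notes name RMA and the affy package without versions, and they do not state which arrays were normalized together. The scanner files were not used here.

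The 64 control probe sets were left out, and 45037 others remained. The platform annotation gave a single gene symbol for 34945 probe sets, several for 932 and none for 9160, and those with several or none were left out of the gene tests. The probe set with the highest mean log2 value over the 12 arrays stood for its gene, which gave 18193 genes, 9010 of them with more than 1 probe set. A model of 4 group means was fitted to the deposited values of all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (8 residual and 5.6 prior degrees of freedom). No filter on dim genes was used. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were pregnant minus virgin in lung and in liver, the difference between these changes (lung minus liver), and virgin lung minus virgin liver.

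The 39 gene lists held 1141 members, of which 1023 were on the array. They were tested with camera of limma with a preset correlation of 0.01 between genes, two-sided, adjusted over the lists within a contrast, and again with a correlation estimated from the data. The second test also rests on the 8 residual degrees of freedom, which the first does not. A lost call is thus not due to correlation alone. For the liver bile acid list the estimated correlation was -0.00179, below the preset, yet the camera p went from 1.13e-07 to 0.000299. In lung 22 lists were called and 1 was called with an estimated correlation, in liver 11 and 4, and in the difference between tissues 11 and 1. Members were counted after adjustment over all genes and after adjustment over the list alone. Array controls were compared with exact permutation tests and overlaps with Fisher's exact test.

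The design, the tests, the gene lists, the naming rule and all alternatives except those for the labelling batch were chosen before the data were examined. The naming rule took, for each pregnancy contrast, the 12 called genes with the largest rise and the 12 with the largest fall whose groups of pools did not overlap. It added up to 4 called members of each list with the largest change, or up to 2 with the smallest p where none was called. For the difference between tissues it took the 12 largest called differences, and for the virgin tissues up to 4 members each of the lung epithelium and hepatocyte lists. Genes named outside this rule (S100a8 in lung, the liver values of prolactin genes, further pancreas, cell cycle, erythroid and imprinted genes, and the tissue differences of genes named for a change in 1 tissue) were chosen after their values were seen. Among the 24 lung genes with the largest rises and falls, 10 had 11 further probe sets, of which 1 had the opposite sign and 6 differed in call. In liver 10 of 24 had 20 further probe sets, of which 2 had the opposite sign and 6 differed in call, and none was called in the opposite direction in either tissue.

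Alternatives changed 1 choice at a time: the arrays in the fit, a filter on dim probe sets, the mean of all probe sets of a gene, probe sets without shared-sequence suffixes, all probe sets, centring each array on its median, quantile normalization over all arrays or within tissue, a variance trend with robust moderation, array weights, pool number as a block, stricter thresholds and leaving out each array. A block for the liver arrays without spike-in signal, treated as a labelling batch, and fits without both liver pools 3, were added after the spike-in signal was seen. Lists of imprinted growth genes and of fetal liver genes were added after the liver values were seen. The steps were tested on simulated data with known changes. At 18193 genes the fit recovered 35.8% of seeded log2 changes of 0.5, 92.5% of those of 1 and 100% of those of 2 in the lung design, with 2.56% false calls. In the liver design it recovered 46.3%, 89.6% and 100%, with 2.48% false calls. Both runs drew normal noise with 1 spread per gene shared by all groups, so they differ only in the random draw. In the data the median SD between arrays was 0.11 in virgin and 0.103 in pregnant lung. It was 0.127 in virgin and 0.144 in pregnant liver, and the simulation does not test such unequal spread. The 1 seeded list was called and 0 other lists were. The simulated noise was independent between genes, so this does not test list calls where genes are correlated. In the data the estimated correlation of the seeded list, cell cycle, was 0.313. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.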

Results

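Lung and liver of female NOD/SCID mice, an immunodeficient strain that lacks mature T and B cells, were profiled on 12 one-colour expression arrays. The mice were 8 to 10 weeks old and either virgin or at day 16 of gestation. Each of the 4 groups (lung virgin, lung pregnant, liver virgin, liver pregnant) held 3 arrays, and each array measured a pool of RNA from 2 mice. The p-values of single genes therefore measure the spread between pools, and the number of arrays limits the precision. The deposited log2 values covered 45037 probe sets other than controls, from which 18193 genes were tested with limma. The array medians lay between 4.491 and 4.559. Correlations between arrays of the same group were 0.9892 to 0.9961, and those between lung and liver arrays were 0.8415 to 0.8538.

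Probe sets for the poly-A spike-in, RNA added before labelling, had a mean log2 value of 11.93 to 12.41 on 10 arrays. The mean was 4.986 on the array of virgin liver pool 3 and 5.197 on that of pregnant liver pool 3. The labels name no batch, but these arrays, 1 of each state, were treated as one. The medians of the called liver lists are therefore given also within pools 1 and 2 and within pool 3, as are the changes of some named liver genes that differed between them by over 1.5 times. The hybridisation controls had a mean log2 value of 9.40 ± 0.178 in pregnant and 9.05 ± 0.0464 in virgin liver (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). The Gapdh difference between 3′ and 5′ probe sets, a sign of RNA integrity, was 0.557 ± 0.121 in pregnant and 0.461 ± 0.178 in virgin liver (SD, n = 3, exact permutation p = 0.6). In lung it was 0.441 ± 0.128 and 0.481 ± 0.212 (SD, n = 3, exact permutation p = 0.9). These tests belong to a family of 10, whose Benjamini-Hochberg adjusted values for these 3 were 0.5, 0.75 and 1.

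The comparison of virgin lung with virgin liver asked whether each tissue carried its own transcripts. All 25 measured members of the lung epithelium list were higher in lung, with a median log2 difference of 6.53. Scgb1a1, a secretory protein of airway club cells, differed by 10.33 ± 0.20 (SE, n = 3 pools per group, limma adjusted p = 6.1e-15), and the surfactant protein genes Sftpc and Sftpa1 by 9.93 and 9.85. All 22 measured members of the hepatocyte list were lower in lung, with a median of -9.33. The antithrombin gene Serpinc1 differed by -10.42 ± 0.11 (adjusted p = 1.98e-17), and the apolipoprotein genes Apob and Apoa2 by -10.15 and -9.88. In total 12501 genes differed between the virgin tissues, 6240 of them higher in lung and 6261 lower.

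The lung comparison asked what pregnancy changed in the lung at day 16. Prl8a2, which encodes a prolactin-related protein of the decidua, showed the largest rise among the called genes. Its level went from a log2 value of 2.90 ± 0.074 in virgin to 5.58 ± 0.069 in pregnant lung (SD, n = 3), a log2 change of 2.68 ± 0.13 (SE, limma adjusted p = 2.26e-07). The placental prolactin family members Prl7b1 and Prl2a1 rose as well, by 1.59 ± 0.27 and 1.07 ± 0.22 (log2, SE, adjusted p = 0.0214 and 0.0428), at low levels: Prl7b1 went from 2.43 to 4.02 and Prl2a1 from 3.78 to 4.85. Lox, the enzyme that cross-links collagen and elastin, rose 3.82-fold (log2 1.93 ± 0.19, adjusted p = 0.000472). Fst, which encodes the activin-binding protein follistatin, rose 3.72-fold (log2 1.89 ± 0.15, adjusted p = 5.01e-05), and Slfn4, a Schlafen family gene of myeloid cells, rose 3.78-fold (adjusted p = 0.00413).

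Lrat, which makes the storage form of retinol, showed the largest fall among the called lung genes and was 2.83-fold lower in pregnant lung (log2 SE 0.11, n = 3 pools per group, adjusted p = 1.3e-05). The replication licensing gene Cdc6 changed by -1.23 ± 0.16 (adjusted p = 0.00403), and Phex, an endopeptidase gene of phosphate balance, by -1.19 ± 0.12 (adjusted p = 0.000485). Mdk, which encodes the growth factor midkine, changed by -1.01, the carboxypeptidase-like gene Cpxm1 by -1.07, the microfibril gene Mfap4 by -0.98 and Shisa2 by -0.93, with adjusted p from 0.000485 to 0.00702. The amino acid transporter gene Slc38a5, the chemokine gene Cxcl14 and Glb1l3 fell by 1.23, 1.17 and 0.97 (adjusted p = 0.0349, 0.0114 and 0.0214). Rbp7, a retinol-binding protein gene, and Adm, which encodes the vasodilator adrenomedullin, rose by 1.38 and 1.09 (adjusted p = 0.0349 and 0.0263).

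In total 108 genes changed in lung, 47 up and 61 down, of which 22 changed at least 2-fold. The groups of pools did not overlap for any of these 108, and for 3356 of all genes tested (18.4%, where chance gives 10%). The number of calls rested on single arrays: it was 26 without virgin pool 2, 36 without virgin pool 3, 50 without pregnant pool 1 and 50 without pregnant pool 2. Of the 45 called lung genes that the naming rule selected, Prl8a2, Lox, Slfn4, Fst, Lrat, Cdc6, Phex, Cpxm1, Mdk, Mfap4, Shisa2 and Fkbp5 passed the test whichever single lung array was left out, and the other 33 lost their call at least once. Their highest adjusted p in these 6 fits ran from 0.0592 for Ntrk2 to 0.204 for Nusap1, reached without virgin pool 1, 2 or 3 or pregnant pool 1. Prl7b1 passed in 2 of these 6 fits (highest adjusted p = 0.0824, without virgin pool 3) and Prl2a1 in 0 of 6 (highest 0.164, without virgin pool 2). Prl7b1, Prl2a1, S100a9, Clec4d, Clec4e, Angptl4, Pdk4, Adm, Rbp7 and Tk1 also lost their calls when the 6 lung arrays were fitted alone. With the mean of all probe sets of a gene Nusap1, Ptges, Bpgm, Tdo2 and Ntrk2 lost their calls. Both levels of Prl7b1 and Tdo2, the virgin levels of Prl8a2, Prl2a1 and Rbp7 and the pregnant levels of Cdc6, Phex, Tk1 and Glb1l3 lay below 4.6, the median level of all probe sets, where signal above background is not shown.

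Neutrophil genes were higher in pregnant lung as a group (camera, a test of a list against all other genes, adjusted p = 1.94e-13, and adjusted p = 0.179 with an estimated correlation). Of 33 measured members 3 rose, 0 fell and 30 did not pass, and 12 rose when adjusted over the list alone. The lectin receptor genes Clec4d and Clec4e rose by 1.12 ± 0.23 and 1.11 ± 0.19 (log2, SE), and S100a9, which encodes a calcium-binding protein abundant in neutrophils, by 1.07 ± 0.18. Its partner S100a8 had a change of 0.89 that did not pass (adjusted p = 0.0558; a gene singled out after its values were seen). Without virgin pool 3 the adjusted p rose to 0.178 for Clec4d, 0.0887 for Clec4e and 0.0824 for S100a9. The platelet and megakaryocyte list was higher too, with a median of 0.46 (adjusted p = 1.09e-10, and adjusted p = 0.179 with an estimated correlation). None of its 18 members passed over all genes and 9 rose when adjusted over the list alone. The integrin gene Itga2b had a change of 0.44 (adjusted p = 0.114) and the platelet receptor gene Clec1b one of 0.87 (adjusted p = 0.164). The myeloid suppressor list was higher (adjusted p = 0.00112, and adjusted p = 0.179 with an estimated correlation), with S100a9 up and the prostaglandin synthase gene Ptges down by -0.75.

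The glucocorticoid response list was higher in pregnant lung, the only list of the 22 called in lung to pass also with an estimated correlation (adjusted p = 3.4e-09, and 0.0138 with an estimated correlation). Of its 23 members 3 rose, 0 fell and 20 did not pass, and 6 rose when adjusted over the list alone. Fkbp5, which encodes a chaperone of the glucocorticoid receptor, rose by 0.67 ± 0.10 (log2, SE, adjusted p = 0.0073). Angptl4, which encodes an inhibitor of lipoprotein lipase, rose by 1.56 ± 0.26 (adjusted p = 0.0202, 0.102 without virgin pool 2), and Pdk4, the kinase that shuts down pyruvate dehydrogenase, by 1.38 ± 0.27 (adjusted p = 0.0369, 0.167 without virgin pool 3). With the mean of its probe sets Fkbp5 changed by 0.21, and with suffixed probe sets left out Angptl4 changed by 0.25, and neither passed. Pdk4 also stood in the fatty acid oxidation list, where Acot1 and Acaa1b rose by 0.99 and 0.67 and 30 of 33 members did not pass. That list was higher (adjusted p = 0.0021, adjusted p = 0.345 with an estimated correlation, and 0.0654 without pregnant pool 2). The immediate early list, whose genes also respond to tissue handling, was higher with a median of 0.30 (adjusted p = 1.09e-10, and adjusted p = 0.138 with an estimated correlation). None of its 25 members passed over all genes and 6 rose when adjusted over the list alone; Atf3 had a change of 0.59 (adjusted p = 0.0558) and Socs3 one of 0.51 (adjusted p = 0.12). The acute phase list was higher (adjusted p = 0.000644, and adjusted p = 0.183 with an estimated correlation), and the protease inhibitor gene Serpina3n rose by 0.60.

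Cell cycle genes were lower in pregnant lung, with a median log2 change of -0.39 over 63 members (adjusted p = 8e-17, and adjusted p = 0.179 with an estimated correlation). Over all genes 0 rose, 3 fell and 60 did not pass, and 12 fell when adjusted over the list alone. Cdc6 fell in each of the 6 fits without 1 lung array. The thymidine kinase gene Tk1 changed by -0.97 ± 0.17 and the spindle gene Nusap1 by -1.05 ± 0.21 (log2, SE), and without virgin pool 2 their adjusted p was 0.108 and 0.204. Cholesterol synthesis genes were lower with a median of -0.15 (adjusted p = 0.001, and adjusted p = 0.25 with an estimated correlation). None of the 22 passed singly; the changes of Dhcr7 and Tm7sf2 were -0.41 and -0.38 (adjusted p = 0.208 and 0.243).

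The extracellular matrix list was lower in lung although Lox rose (adjusted p = 0.0203, and adjusted p = 0.376 with an estimated correlation). Mfap4 was the other member of the 38 to pass, downwards, and 3 rose and 11 fell when adjusted over the list alone. The call was lost without pregnant pool 2 (adjusted p = 0.381), without virgin pool 2 (0.0555) and without virgin pool 3 (0.0699). The natural killer cell list was lower (adjusted p = 0.0203, and adjusted p = 0.341 with an estimated correlation). None of its 30 members passed; the receptor genes Klrk1 and Klrb1f had changes of -0.68 and -0.56 (adjusted p = 0.232 and 0.315). Its call was lost without pregnant pool 1 (adjusted p = 0.195), without virgin pool 3 (0.0765) and without pregnant pool 3 (0.126), and with dim probe sets left out (0.0724). The erythroid list was lower (adjusted p = 0.0081, and adjusted p = 0.179 with an estimated correlation, 0.0852 without pregnant pool 1), and its members Trim10 and Bpgm fell by 0.60 and 0.59. Antigen presentation genes were lower (adjusted p = 0.0203, adjusted p = 0.179 with an estimated correlation, 0.0767 without pregnant pool 1, 0.0597 without virgin pool 1 and 0.138 with dim probe sets left out), with Siglech at -0.64 (adjusted p = 0.102).

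**Figure D1:**
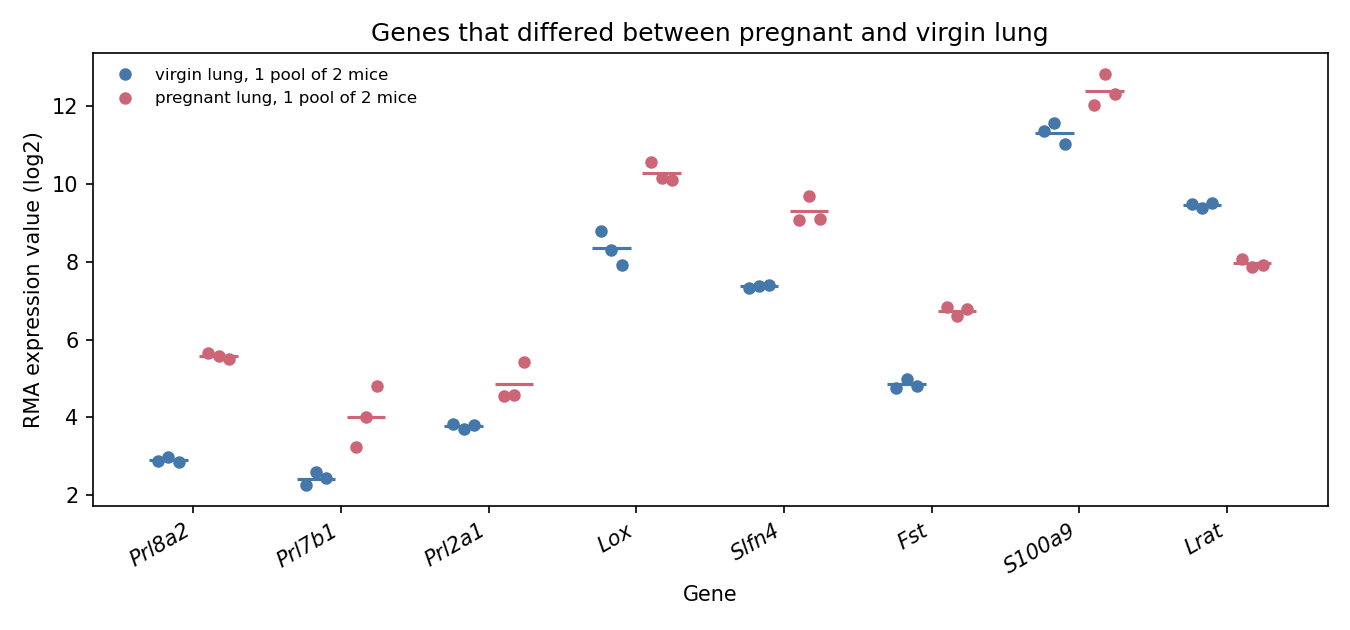
Deposited log2 values of the named lung genes in virgin and pregnant lung, with a point for each pool (n = 3 per group) and a bar for each mean. Prl8a2 moved from 2.90 to 5.58.

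The liver comparison asked what pregnancy changed in the liver at day 16. A2m, which encodes the protease inhibitor alpha-2-macroglobulin, rose from a log2 value of 3.79 to 10.41 (log2 change 6.62 ± 0.12, SE, n = 3 pools per group, limma adjusted p = 5.36e-13). Its change was 6.49 within pools 1 and 2 and 6.88 within pool 3. The monocarboxylate transporter family gene Slc16a6 and the sugar-phosphate exchanger family gene Slc37a1 rose 19.7-fold and 16.4-fold, and the calcium channel gene Cacna1h rose by 4.13 (log2). The lens crystallin gene Crybb3, the magnesium transporter gene Slc41a2 and the co-chaperone gene Dnajc12 rose 13.9-fold, 12.5-fold and 11.6-fold, and the neuronal pentraxin gene Nptx1 and Ripor2 rose by 3.87 and 3.71 (log2). Peg3, an imprinted gene, rose 9.07-fold (adjusted p = 8.41e-10). The virgin levels of A2m, Cacna1h, Nptx1, Ripor2, Pnliprp1, Chil3, Birc5 and Hmmr and the pregnant levels of Bmf, Ugt2b37 and Cxcl14 lay below 4.6, where signal above background is not shown.

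Cyp4a14, a fatty acid hydroxylase gene, showed the largest fall among the called liver genes, with a log2 change of -3.91 ± 0.29 (SE, n = 3 pools per group, adjusted p = 6.24e-07). The export pump gene Abcc3 changed by -3.18 ± 0.12, the lysophospholipid transporter gene Mfsd2a by -2.98 ± 0.23 and Ddah1, whose enzyme breaks down a nitric oxide synthase inhibitor, by -2.90 ± 0.14. The complement gene C9, the small heat shock protein gene Hspb1, the chemokine gene Cxcl14 and the steroid dehydrogenase gene Hsd3b2 changed by -2.51, -2.41, -2.34 and -2.12. The phosphate transporter family gene Slc17a2, the glucuronosyltransferase gene Ugt2b37 and Serpina4-ps1 changed by -2.63, -2.56 and -3.12. Bmf, which encodes a promoter of cell death, changed by -3.71, but by -0.36 and without passing when probe sets with shared-sequence suffixes were left out. These 24 genes with the largest rises and falls passed whichever single liver array was left out.

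In total 2482 genes changed in liver, 1096 up and 1386 down, or 13.6% of those tested, and 326 changed at least 2-fold. The groups of pools did not overlap for 2428 of these and for 28% of all genes, where chance gives 10%. Of the 2482 changes, 2476 had the same sign within pools 1 and 2 and within pool 3, and 6 had the opposite sign within pool 3. For the 2428 genes whose groups did not overlap the same sign was fixed in advance. The agreement in sign therefore does not test an effect of the pool 3 arrays. Of the 130 called liver genes that the naming rule selected, 97 passed whichever single liver array was left out. The changes within pools 1 and 2 and within pool 3 had the same sign for all 130, again fixed wherever the groups did not overlap. For 98 they were within 1.5 times of each other. Serpina4-ps1 changed by -2.62 within pools 1 and 2 and by -4.13 within pool 3, Fgf21 by 0.91 and 2.94, Birc5 by 1.04 and 2.16, Hmmr by 1.13 and 1.72, and Slco1a4 by -0.73 and -1.74. Chil3 changed by 2.11 and 1.21, Elovl6 by -2.01 and -1.30, Cyp2b13 by -1.83 and -1.20, Mt2 by 1.56 and 2.34, Slc7a2 by -0.58 and -1.01, and Tmem97 by 0.88 and 1.5.

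The cholesterol synthesis list was lower in pregnant liver. Of 22 members 19 fell, 1 rose and 2 did not pass, and 20 fell when adjusted over the list alone (camera adjusted p = 1.53e-15, and 0.0295 with an estimated correlation). The median log2 change was -0.67, with -0.74 within pools 1 and 2 and -0.58 within pool 3. Lss, the lanosterol synthase gene, changed by -1.44 ± 0.13, Pmvk of the mevalonate pathway by -1.37 ± 0.18 and the farnesyl diphosphate synthase gene Fdps by -1.01 ± 0.13 (SE, n = 3). Tmem97, a sterol-responsive membrane protein gene, rose by 1.09. The fatty acid and triglyceride synthesis list was lower too, with 18 of 29 down, 2 up and 9 not passing (adjusted p = 1.37e-12, and 0.0267 with an estimated correlation). Their median was -0.55, with -0.48 within pools 1 and 2 and -0.68 within pool 3. The malic enzyme gene Me1, the elongase gene Elovl6 and the citrate lyase gene Acly changed by -1.81 ± 0.11, -1.77 ± 0.13 and -1.58 ± 0.12, and Mid1ip1, a regulator of acetyl-CoA carboxylase, by -1.68.

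The bile acid list was lower, with 14 of 32 down, 1 up and 17 not passing (adjusted p = 8.83e-07, and 0.0116 with an estimated correlation; median -0.31 within pools 1 and 2 and -0.38 within pool 3). The sterol exporter gene Abcg5 changed by -1.29 ± 0.10 and the uptake transporter gene Slco1a4 by -1.07 ± 0.18 (SE). Slc10a1, the main bile salt uptake transporter gene, changed by -0.94 ± 0.24 (adjusted p = 0.0196, 0.061 without virgin pool 1). The list of amino acid, urea and glucose metabolism was lower, with 9 of 35 down, 1 up and 25 not passing (adjusted p = 3.3e-05, and 0.0267 with an estimated correlation; median -0.23 within pools 1 and 2 and -0.33 within pool 3). Prodh, the proline dehydrogenase gene, changed by -1.69 ± 0.12, the amino acid transporter gene Slc38a4 by -1.48 ± 0.17, the glucose transporter gene Slc2a2 by -1.14 ± 0.11 and Slc7a2 by -0.72. Oxidative phosphorylation genes were lower, with 8 of 27 down, 0 up and 19 not passing, and 20 down when adjusted over the list alone (adjusted p = 8.14e-07, and adjusted p = 0.4 with an estimated correlation; median -0.33 within pools 1 and 2 and -0.16 within pool 3). Ndufs7 of complex I changed by -0.57 and Cox7a2 of complex IV by -0.53 (-0.21 and not passing with suffixed probe sets left out).

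Drug and steroid metabolism genes were lower as a list while members went both ways, with 18 of 56 down, 7 up and 31 not passing (adjusted p = 0.00879, and adjusted p = 0.172 with an estimated correlation, 0.0811 with dim probe sets left out; median -0.23 within pools 1 and 2 and -0.21 within pool 3). Cyp17a1, an enzyme gene of androgen synthesis, and Cyp3a16 rose by 1.97 ± 0.17 and 1.64 ± 0.15, and Cyp2b13 and the monooxygenase gene Fmo5 changed by -1.62 ± 0.25 and -1.37 ± 0.09 (log2, SE). In the fatty acid oxidation list, which did not pass (adjusted p = 0.169), 6 of 33 members rose and 3 fell. The pantetheinase gene Vnn1 rose by 2.08 ± 0.17, and the fasting hormone gene Fgf21 by 1.59 ± 0.37, or by 0.973 without pregnant pool 3. The growth hormone and prolactin list did not pass either (adjusted p = 0.136), with 8 of 24 members up and 2 down. The growth factor gene Igf2 rose by 3.06 ± 0.48 (adjusted p = 0.000651), its binding protein gene Igfbp1 by 1.71 ± 0.17 and the growth hormone receptor gene Ghr by 1.03 ± 0.08. The Igf2 level varied between the pregnant pools, with log2 values of 9.63, 6.63 and 8.48.

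Acute phase genes were higher in pregnant liver, with 10 of 33 up, 2 down and 21 not passing (adjusted p = 1.29e-07, and adjusted p = 0.1 with an estimated correlation; median 0.30 within pools 1 and 2 and 0.42 within pool 3). The metallothionein genes Mt2 and Mt1 rose by 1.82 ± 0.20 and 1.61 ± 0.16 and the interleukin-6 receptor gene Il6ra by 1.32 ± 0.17 (log2, SE). Hamp, which encodes the iron hormone hepcidin, changed by -1.29 ± 0.31 (adjusted p = 0.0133, 0.0502 without pregnant pool 1). Endoplasmic reticulum stress genes were higher, with 12 of 30 up and 18 not passing (adjusted p = 8.85e-07, and adjusted p = 0.149 with an estimated correlation; median 0.28 within pools 1 and 2 and 0.26 within pool 3). Creld2 rose by 1.44 ± 0.14, the disulfide isomerase gene Pdia6 by 1.08 ± 0.12 and Sel1l, of the degradation machinery, by 0.67. Immediate early genes were higher, with 8 of 25 up and 17 not passing (adjusted p = 0.00281, and adjusted p = 0.4 with an estimated correlation, 0.0524 without both pools 3; median 0.16 within pools 1 and 2 and 0.34 within pool 3). Egr1 rose by 3.62 ± 0.39 and Fos by 2.21 ± 0.33, both transcription factor genes, and the growth arrest gene Gadd45b rose by 1.53 ± 0.10. Egr1 varied between the virgin pools, with log2 values of 6.99, 8.36 and 6.59. Genes of this list also respond to tissue handling, and an effect of handling was not tested.

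Cell cycle genes were higher in pregnant liver, with a median log2 change of 0.31 over 63 members, 0.26 within pools 1 and 2 and 0.49 within pool 3 (adjusted p = 4.68e-06, and adjusted p = 0.564 with an estimated correlation). Over all genes 16 rose, 2 fell and 45 did not pass, and 24 rose when adjusted over the list alone. The mitotic gene Hmmr rose by 1.33 ± 0.24 (0.25 and not passing with suffixed probe sets left out). Birc5, which encodes survivin, rose by 1.41 ± 0.42 (adjusted p = 0.0411, 0.162 without virgin pool 1) and the cyclin gene Ccnb2 by 1.36 ± 0.36 (0.0233, and 0.0801 without pregnant pool 3). Without 1 liver array their log2 changes ran from 0.946 to 1.88 and from 0.825 to 1.76. Mcm10, a replication gene, changed by -1.22 ± 0.21, and Tk1 was the other member that fell. Neutrophil genes were higher, with 6 of 33 up and 27 not passing (adjusted p = 0.000806, and adjusted p = 0.564 with an estimated correlation; median 0.21 within pools 1 and 2 and 0.22 within pool 3). The chitinase-like gene Chil3 rose by 1.81 ± 0.14 and S100a9 by 1.28 ± 0.18, and S100a8 rose 2.83-fold (adjusted p = 0.000119). The granule protein gene Ngp rose by 1.89 ± 0.48 (adjusted p = 0.0185, 0.0674 without virgin pool 3).

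A number of called liver genes stood in lists that did not pass. Pnliprp1 and Cela3b, lipase-related and elastase-type genes of the exocrine pancreas, rose by 3.42 ± 0.19 and 2.73 ± 0.10 (log2, SE, adjusted p = 3.57e-08 and 5.31e-10), while the elastase genes Cela1 and Cela2a changed by -1.35 and -0.87 (list adjusted p = 0.115). In the natural killer cell list 4 of 30 members fell and 1 rose (adjusted p = 0.479). The granzyme gene Gzmb changed by -0.70 ± 0.12 (adjusted p = 0.000962) in pregnant liver. Fasl and Klrc1 changed by -0.43 and -0.41 at levels below 4.6 in both states, calls that other choices of probe set ended, with adjusted p of 0.128 without pregnant pool 1 and 0.111 without virgin pool 1. In the erythroid list 4 members rose and 4 fell (adjusted p = 0.547), among them the transferrin receptor gene Tfrc and the heme synthesis gene Alas2, up by 1.51 and 1.16. The platelet chemokine gene Ppbp rose by 2.02 ± 0.23 (list adjusted p = 0.195). The von Willebrand factor gene Vwf, the 1 of 30 endothelium list members to rise, rose by 2.48 ± 0.15, while Car4, at levels below 4.6 in both states, Ptprb and Kdr changed by -0.48, -0.34 and -0.30 (list median -0.12, adjusted p = 0.394). Leaving out 1 liver array ended the calls of these 3 (highest adjusted p = 0.112 without virgin pool 3 for Car4, and 0.0697 and 0.15 without pregnant pool 2 for Ptprb and Kdr). Car4 changed by -0.28 within pools 1 and 2 and by -0.86 within pool 3. None of the 23 trophoblast and placenta list members passed in liver (adjusted p = 0.547) or in lung (adjusted p = 0.32).

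**Figure D2:**
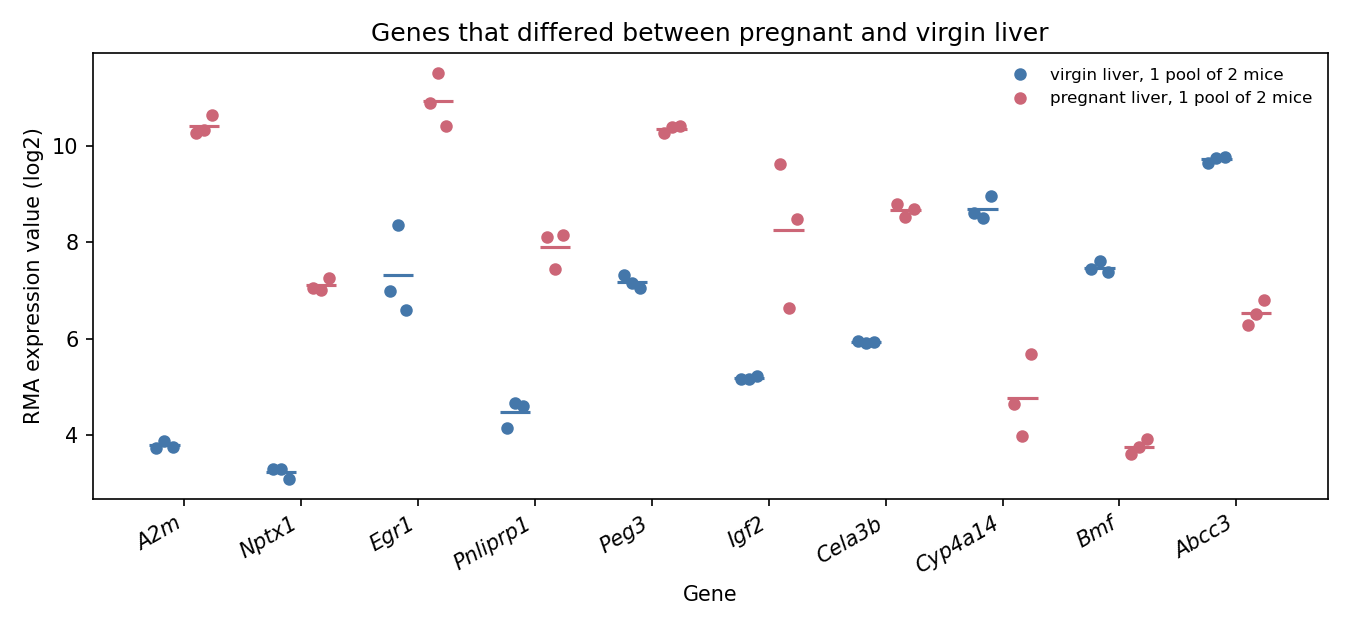
Deposited log2 values of the named liver genes in virgin and pregnant liver, with a point for each pool (n = 3 per group) and a bar for each mean. A2m moved from 3.79 to 10.41.

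The last comparison asked whether pregnancy changed lung and liver alike. Among the 26 genes called in both tissues, 7 rose in both, where independent lists would share 2.83 (Fisher's exact p = 0.0215), and 12 fell in both, where independent lists would share 4.65 (Fisher's exact p = 0.00192). Fisher's test counts genes as independent, which they are not. Both call lists also came from 1 fit with a shared estimate of the spread per gene, which can by itself raise the overlap. The 19 genes called in the same direction became 9 with each tissue fitted alone and 1 at an adjusted p under 0.01. S100a9, Serpina3n and Fkbp5 were among those that rose and Lrat, Cxcl14 and Tk1 among those that fell. Fst rose in lung and fell in liver. Across all genes, which are not independent replicates, the changes in both tissues had a Pearson r of 0.0654 and a Spearman rho of 0.0552.

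The change differed between lung and liver for 1221 genes, with 608 more positive in lung and 613 more positive in liver (limma interaction term). The labels do not say whether same-numbered lung and liver pools came from the same mice, and the fit treated all pools as independent. With same-numbered pools of a state as a random block the count was 1300, at a consensus correlation of 0.0303. A2m had the largest difference, at -6.64 ± 0.17 for lung minus liver (log2, SE, n = 3 pools per group, adjusted p = 5.53e-11). Prl8a2 differed by 2.53 ± 0.18 (adjusted p = 1.57e-06) and Prl7b1 by 1.68 ± 0.38 (adjusted p = 0.0172), while the difference of 0.94 ± 0.31 for Prl2a1 did not pass (adjusted p = 0.0896). Fst differed by 2.56 and Cdc6 by -1.69 (adjusted p = 5.85e-06 and 0.000387). The differences of Lrat, Tk1 and S100a9 were -0.05, -0.15 and -0.21 and did not pass (adjusted p = 0.91, 0.784 and 0.701).

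Of the gene lists, 11 had a pregnancy change that differed between the tissues. The change of the cell cycle list was more negative in lung, with a median lung change minus liver change of -0.65 (camera adjusted p = 2.46e-15, and adjusted p = 0.3 with an estimated correlation). Of its members 17 passed, each with a more positive change in liver. Cholesterol synthesis genes differed by a median of 0.55 and fatty acid synthesis genes by 0.66, each more positive in lung (adjusted p = 1.99e-10 and 3.15e-10, and adjusted p = 0.105 and 0.0742 with an estimated correlation). The bile acid list differed by 0.35 (adjusted p = 7.89e-05, and 0.0359 with an estimated correlation), the 1 list of the 11 to pass with an estimated correlation. The neutrophil list did not differ past the threshold (adjusted p = 0.634).

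**Figure D3:**
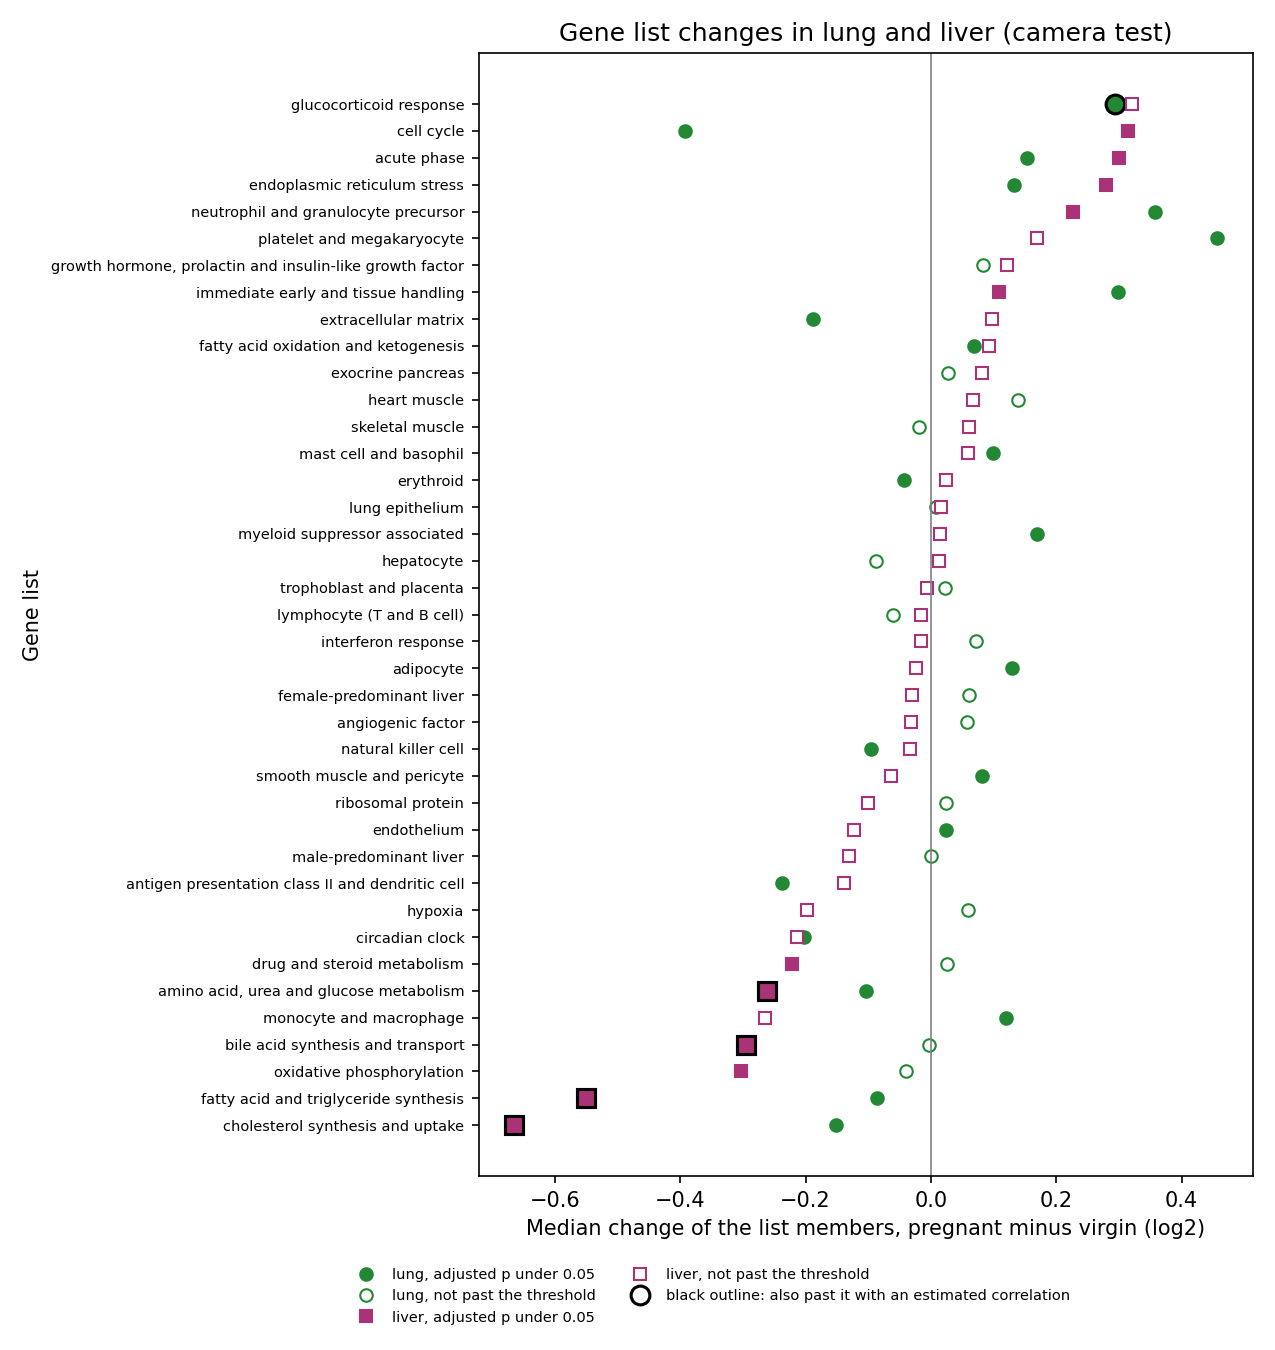
Median log2 change, pregnant minus virgin, of the members of each of the 39 gene lists in lung (circles) and liver (squares), filled where the camera adjusted p was under 0.05. The cell cycle list lay at -0.39 in lung and 0.31 in liver.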

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

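The tests on the trophoblast, erythroid and exocrine pancreas lists, and those on the liver values of Prl8a2, Prl7b1 and Prl2a1, were chosen after the results they address were seen. The bootstrap intervals here and below resampled the members of a list, which are not independent, and they hold no spread between pools.

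The response to pregnancy differed between lung and liver for 1221 genes by the interaction term. When the arrays were regrouped within each tissue, 2 of 100 drawn splits out of 200 possible gave as many genes, the real one included, a share under 0.05. The count follows the liver groups: the highest other split, with 1589 genes, had both real groupings with the liver labels swapped, the 8 drawn splits with the real liver groups and other lung groups gave 809 to 1039, and the highest without the real liver groups gave 5. The share thus rests on the liver grouping, which 10 of the 100 drawn splits kept, and it does not exclude chance for a difference between the tissues. In lung the real groups gave 108 genes and the highest of the other 9 splits gave 5; in liver the real groups gave 2482 and the highest other gave 1; between the virgin tissues they gave 12501 and the highest other gave 0. In each of these 3 comparisons 1 of 10 splits, the real one, reached its own count, and 10 splits are too few for a share under 0.05.

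The largest differences between the tissues (lung change minus liver change, log2) were -6.64 for A2m, -4.16 for Slc16a6, -4.11 for Slc37a1, -4.05 for Cacna1h, -3.91 for Crybb3 and -3.75 for Egr1. Nptx1 followed with -3.74, Dnajc12 with -3.71, Pnliprp1 with -3.56 and Ripor2 with -3.51, and Cyp4a14 and Bmf differed the other way by 3.94 and 3.72. The Bmf difference was 0.205, and did not pass, with suffixed probe sets left out. The 11 lists whose change differed between the tissues were cell cycle (adjusted p = 2.46e-15), cholesterol synthesis (1.99e-10), fatty acid synthesis (3.15e-10), bile acid (7.89e-05), oxidative phosphorylation (0.000147), drug and steroid metabolism (0.000863), monocyte and macrophage (0.00389), acute phase (0.00461), endoplasmic reticulum stress (0.00805), amino acid, urea and glucose metabolism (0.0156) and extracellular matrix (0.0326). With an estimated correlation the bile acid list alone of the 11 passed (adjusted p = 0.0359). The amino acid list lost its call without virgin liver pool 3 (adjusted p = 0.0626), without both liver pools 3 (0.105) and with dim probe sets left out (0.0544). The extracellular matrix list lost its call without virgin lung pool 2 (adjusted p = 0.0638), virgin lung pool 3 (0.0558), pregnant lung pool 2 (0.198), virgin liver pool 1 (0.106) or pregnant liver pool 3 (0.08). Probe sets with no single gene name, which the gene tests left out, held 9 called in lung and 421 called in liver among 10092.

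Of 17 measured prolactin family members Prl8a2, Prl7b1 and Prl2a1 rose in pregnant lung and 14 did not pass; Prl8a2 alone of these 3 passed in every fit without 1 lung array, Prl7b1, dim in both states, in 2 of 6 and Prl2a1 in 0 of 6. Placental tissue carried over into the samples would bring the transcripts of the trophoblast and placenta list, but its 23 measured members had a median log2 change of 0.0221 in lung (95% bootstrap interval -0.0592 to 0.126), and Tpbpa and Prl8a8, abundant in placenta, changed by 0.02 and -0.17. Of the 30 members written, Prl3b1, Prl3d1, Prl2c2, Prl2c5, Gcm1, Syna and Synb were not among the genes tested, so their change is not known. Blood that carried the transcripts in equal amounts to every organ would raise them in liver too. There Prl8a2 changed by 0.153 (upper bound 0.413) and Prl7b1 by -0.0857 (upper bound 0.458), both below 0.5 times their lung change. For Prl2a1 the liver change of 0.131 has an upper bound of 0.565, above 0.5 times its lung change. For it blood in equal amounts cannot be told apart from a change in lung. How much blood each organ held was not measured. Between the virgin tissues 22 of 33 neutrophil list members were called higher in lung and 4 lower. For platelet members it was 14 of 18 and 1, and for erythroid members 7 of 23 and 8. Of all 18193 genes 6240 were called higher in lung and 6261 lower, a share that the erythroid list was near. The erythroid list thus shows no sign of more blood in lung. The neutrophil and platelet lists leave a larger share of blood in lung open, which the liver values do not exclude. Decidual cells, which the list does not cover, and expression in the lung itself during pregnancy may be the source of Prl8a2, and both remain untested hypotheses.

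Of the 14 measured exocrine pancreas genes Pnliprp1, Cela3b, Clps and Cpa1 rose in pregnant liver, 2 fell and 8 did not pass (list adjusted p = 0.115). Pancreas tissue carried over would raise all of them, but their median log2 change was 0.0815 (95% bootstrap interval -0.0758 to 0.385), with Clps at 0.70, Cpa1 at 0.39, Cpb1 at 0.02, Cel at 0.01 and Prss2 at -0.08. Cela1 and Cela2a, which virgin liver also showed at log2 values of 10.17 and 5.64, fell. The smallest change of Pnliprp1 and Cela3b within pools 1 and 2 or within pool 3 was 2.73, so the rise was present in both parts. Each part held both states and the groups of pools did not overlap for these genes, so a rise in both was fixed in advance. It does not test an effect of a batch of the pool 3 arrays. A candidate explanation is that pregnancy raises Pnliprp1 and Cela3b in the liver itself, a hypothesis found and tested on the same data.

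The cell cycle list was lower in pregnant lung and higher in pregnant liver. The gap between the liver and lung medians was at least 0.665 under 4 scalings, but these hardly moved the medians, so the effect of the deposited normalization stays open; the highest lung median without 1 lung array was -0.323, so no single array accounts for the lower lung list. Erythroid precursors in liver cannot be told apart from other dividing cells. The 16 erythroid list members above the median level in virgin liver had a median of -0.0134 (95% bootstrap interval -0.324 to 0.348). Among them Alas2, Tfrc, Tspan33 and Bpgm rose by 1.16, 1.51, 0.69 and 0.68, while Car1, Slc25a37 and Car2 changed by -0.77, -0.69 and -0.43. Klf1 and Slc4a1, at -0.35 and -0.04, did not pass. The list tests lose their calls with an estimated correlation (adjusted p = 0.179 in lung, 0.564 in liver and 0.3 for the difference), and which cells divide more or less was not tested. A change in dividing cells of each tissue may remain as a hypothesis.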

How the results depend on the processing

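The labelling-batch alternatives were chosen after the spike-in signal was seen. The lung count of 108 became 207 with a variance trend and robust moderation, 313 with array weights, 70 with a pool block within tissue, 22 at 2-fold, 22 at an adjusted p under 0.01, and 26 to 105 without 1 lung array. Stricter thresholds lower counts by construction, and a count over all probe sets has another unit than a count of genes. For the other settings named here the cause was not tested. The liver count of 2482 went to 1557 with the 6 liver arrays alone, 326 at 2-fold and 1321 at an adjusted p under 0.01, and to 1879 to 2541 without 1 array; it was 2721 with a batch block and 2146 without both pools 3. The difference between tissues (1221 genes) went to 372 and 564 at the stricter thresholds and 888 to 1319 without 1 array. Virgin lung against liver (12501 of 18193 genes) gave 25158 of 45037 probe sets when all were tested, and 5040 genes at 2-fold and 11526 to 12109 without 1 array. With an estimated correlation 1 list remained called in lung, 4 in liver and 1 in the difference; without 1 array the counts were 16 to 20, 11 to 13 and 10 to 14. The 19 genes called in both tissues in the same direction became 1 at an adjusted p under 0.01 and 9 with each tissue fitted alone. Aldoc in liver, at -1.32 within pools 1 and 2 and -0.39 within pool 3, reversed to 0.0737 with suffixed probe sets left out; the cause was not tested. Of 572 values of the 45 named lung genes under other settings, 494 kept direction and call and 78 lost the call; without 1 array it was 134 and 136 of 270. In liver 1671 of 1793 kept both and 121 lost the call, with 655 and 125 of 780 without 1 array. The limit from signal over background is at the low end of the scale: with probe sets at or below the median level of 4.6 left out, 12574 genes could be tested.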

Other observations

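The tests on the added imprinted and fetal lists used lists written after the data were seen.

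Single genes passed in further liver lists, and none of the liver lists in this paragraph passed. In pregnant liver the B cell gene Blnk changed by -1.07 (adjusted p = 0.000262) and the macrophage gene Timd4 by -0.64, while their lists did not pass (adjusted p = 0.394 and 0.0742). The B cell genes Ighm and Pax5 were called at -1.57 and -0.37, but changed by -0.18 and -0.14 and did not pass with the mean of their probe sets, and the adjusted p of Pax5 was 0.102 without virgin pool 3. Pax5 changed by -0.30 within pools 1 and 2 and by -0.51 within pool 3. The strain lacks mature B cells, and which cells carried the transcripts of Blnk, Ighm and Pax5 was not tested. Basement membrane collagen genes Col4a2 and Col4a1 rose by 0.84 and 0.78 (Col4a1 by 0.91 within pools 1 and 2 and 0.54 within pool 3) and the matrix protease gene Mmp14 by 1.12 (matrix list adjusted p = 0.394). The growth factor gene Pdgfa rose by 1.81 and Ang, which encodes angiogenin, changed by -1.25 (angiogenic factor list adjusted p = 0.518). Ndrg1 of the hypoxia list rose by 2.66 while Pdk1 changed by -0.80, with -0.91 within pools 1 and 2 and -0.58 within pool 3 (list adjusted p = 0.198). The sex-biased genes Cyp39a1 and Ntrk2, higher in female liver, changed by -1.81 and -1.77, and Nudt7, higher in male liver, by -1.91, while Cyp17a1 of the female list rose by 1.97 and C8a, Cyp7b1 and Gstp1 of the male list by 0.91, 0.81 and 0.63. In the female list 3 members rose and 6 fell (adjusted p = 0.394), and in the male list 3 rose and 4 fell (adjusted p = 0.668). The interferon-induced gene Gbp3 changed by -0.77, with -0.92 within pools 1 and 2 and -0.46 within pool 3 (list adjusted p = 0.732), and in the glucocorticoid list 6 of 23 members rose, 1 fell (adjusted p = 0.0858) and Ddit4 rose by 0.77, with 0.59 within pools 1 and 2 and 1.14 within pool 3. Of the clock genes Nampt changed by -0.65 (list adjusted p = 0.308), and of the lung epithelium list Cyp2f2 changed by -0.70 (0.637). In the myeloid suppressor list (0.394) 2 members rose and 2 fell, and Cd74 changed by -0.72 in the antigen presentation list (0.479; Cd74 at an adjusted p of 0.103 without pregnant pool 1, and at -0.97 within pools 1 and 2 and -0.23 within pool 3). The remaining liver lists did not pass: hepatocyte (0.637), heart muscle (0.584), skeletal muscle (0.397), smooth muscle (0.637), mast cell (0.465), adipocyte (0.736) and ribosomal protein (0.251).

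Values given below without an array are the highest of the 6 fits that leave out 1 array of the tissue. In pregnant lung the interferon-induced genes Oas1a and Oas2 rose by 0.81 and 0.80, with adjusted p of 0.156 and 0.18 without virgin pool 2 (list adjusted p = 0.155). In the angiogenic factor list Angptl4 and Adm rose and Angpt2 changed by -0.78 (list adjusted p = 0.0519). The endothelium list was higher (adjusted p = 0.0351, adjusted p = 0.376 with an estimated correlation, 0.246 without pregnant pool 3), with the TGF-beta co-receptor gene Eng up by 0.50. It passed in 2 of 6 fits without 1 lung array, and its adjusted p was 0.077 with the mean of all probe sets, 0.0986 with quantile normalization within tissue and 0.0662 with a pool block. The mean of all probe sets also ended the calls of the clock list (0.143) and the amino acid and glucose list (0.0947), and leaving out dim probe sets ended that of the adipocyte list (0.0601). The adipocyte and fatty acid synthesis lists passed in 2 of 6 fits without 1 lung array, the mast cell, smooth muscle, monocyte and clock lists in 4, and the endoplasmic reticulum stress and amino acid lists in 5. The mast cell list was higher (0.0263, adjusted p = 0.179 with an estimated correlation, 0.0802 without virgin pool 3), with Gata2 up by 0.70. The adipocyte list was higher (0.0349, adjusted p = 0.325 with an estimated correlation, 0.183 without pregnant pool 1), with the lipase gene Lipe up by 0.86, or by 0.39 and not passing with the mean of its probe sets. The smooth muscle list (0.0276, adjusted p = 0.183 with an estimated correlation, 0.183 without pregnant pool 1), the monocyte list (0.0101, adjusted p = 0.4 with an estimated correlation, 0.183 without pregnant pool 3) and the endoplasmic reticulum stress list (0.0021, adjusted p = 0.25 with an estimated correlation, 0.0537 without pregnant pool 1) were higher with no member past the test. The fatty acid synthesis list (0.0307, adjusted p = 0.34 with an estimated correlation, 0.103 without pregnant pool 2), the clock list (0.0488, adjusted p = 0.34 with an estimated correlation, 0.259 without virgin pool 3) and the amino acid and glucose list (0.0203, adjusted p = 0.179 with an estimated correlation, 0.0522 without pregnant pool 3) were lower. The lists that did not pass in lung were lymphocyte (0.0751), hypoxia (0.0995), drug and steroid metabolism (0.116), female liver (0.117), heart muscle (0.155), growth hormone and prolactin (0.247), oxidative phosphorylation (0.387), hepatocyte (0.51), ribosomal protein (0.54), bile acid (0.54), skeletal muscle (0.902), lung epithelium (0.902), male liver (0.902) and exocrine pancreas (1). Median, mean and test differed in sign for the skeletal muscle and pancreas lists in lung, the trophoblast and angiogenic lists in liver, and the hepatocyte, fatty acid oxidation and immediate early lists in the difference between tissues, and none of these 7 passed.

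Igf2 and Peg3, imprinted genes active in fetal growth, rose in pregnant liver. A hypothesis that imprinted growth genes rose as a group was tested without Igf2 and Peg3 on 15 further members, whose median log2 change was -0.101 (95% bootstrap interval -0.33 to 0.0405), so such a group rise was not seen. A hypothesis of a return to a fetal liver programme was tested without Igf2 on 14 members, whose median was -0.0572 (interval -0.211 to 0.0764), and was not borne out. Of the 17 measured imprinted members with these included 4 rose and 3 fell, and of the 15 fetal liver members 3 rose and 1 fell.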
